A study of Mus musculus with 33 samples.

How the data were processed

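The labels describe cultured esophageal basal cells of mice homozygous for a floxed Nudt21 allele and carrying a tamoxifen-inducible Cre recombinase. Control cells received ethanol for 4 days, KO cells 0.05 uM 4-hydroxytamoxifen for 2, 4 or 6 days, and hypomorph cells 0.05 uM 4-hydroxytamoxifen with 50 ng/ml doxycycline for 4 or 6 days. All and only hypomorph samples had doxycycline, so its effect cannot be separated from the hypomorph state. How it acts on Nudt21 is not given here. Messenger RNA was sequenced from poly(A)-selected directional libraries (14 PCR cycles) in 18 samples, 3 in each of 6 groups. PAS-seq covered 9 samples and small RNA sequencing 6 samples, 3 in each group. Which exon is deleted is not given either.

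Per the submitters' processing notes, mRNA reads were aligned to mm10 with STAR and counted with featureCounts, PAS-seq reads were aligned to mm9 with STAR and counted with featureCounts, and small RNA reads were processed with STAR, Bowtie, Subread, SAMtools, featureCounts and edgeR on mm10. No tool versions were given, and the test behind the authors' mRNA comparisons was not stated. The deposited mRNA table holds a normalized signal per gene and library, and beside it the authors give a log2 change and a p-value for each comparison with day 0. The design assumed CPM (reads scaled to a fixed library total), but the column totals of the deposited table differ between libraries and from that of CPM, so the values are called signal by the deposited table's own scale and are used here as CPM scaled by the authors, written scaled CPM. The deposited PAS-seq table holds a ratio of proximal to distal site use per gene, pooled over the samples of a group, with the authors' call. The deposited small RNA table holds a signal per miRNA and sample, with the authors' log2 change, p-value and call.

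Read counts were recovered from the mRNA signal as whole numbers (100% of values within 0.1 of a whole read), giving 16.3 to 91.4 M (mega) reads per library on 12348 listed genes. No unique molecular identifiers were described. Gene positions came from the GRCm38 reference table, to which 11770 of the 12348 symbols were matched. PAS ratios were turned into a proximal share in percent. The hypomorph ratio equalled the KO ratio, within 1e-06, in 3397 of 4324 genes, so the hypomorph ratios were left out and the authors' hypomorph calls kept as deposited. Their ratio of ratios was KO over control in every gene, but for the hypomorph it was control over hypomorph in 3437 genes (79.5%) and neither way round in 886, so the direction of the hypomorph calls rests on the authors. In the small RNA table the 3 columns of each group were identical, so 1 column per group was used and the other 4 were left out. No miRNA target list was available, and miRNA targets are not analysed here.

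Differences in mRNA were tested two-sided with limma 3.58.1 in R 4.3.3 on log2(scaled CPM + 0.5), with a mean-variance trend and robust empirical Bayes, for genes at 1 or more CPM in at least 3 libraries, in one fit of all 18 libraries with a term per group. Benjamini-Hochberg (BH) adjusted p under 0.05 was the threshold. The 7 comparisons were KO day 2, 4 and 6 and hypomorph day 4 and 6 against day 0, and hypomorph against KO at days 4 and 6, with the interaction of day (6 against 4) and state. Gene lists (26, written before the data were examined, as were 9 miRNA lists, the comparisons, the thresholds and the tests) were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Lists with fewer than 3 tested members are given gene by gene.

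The genes named were chosen by a rule: Nudt21; in each mRNA comparison the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out provisional symbols, pseudogenes and mitochondrial genes; and from each list that was called or had at least 3 members past the threshold the 3 members with the smallest p. For PAS-seq the rule took the 5 largest shifts each way among called genes and all listed CFIm25 targets, and for miRNAs the 8 largest changes each way among called miRNAs with a mean of at least 50 scaled CPM. The lists cover  Some genes that the rule picks are not reported here by name, but remain in the counts and gene lists. The gene lists were cleavage and polyadenylation factors, CFIm25 3' UTR targets, miRNA biogenesis and effector genes, basal epithelial cell markers, squamous differentiation genes, Notch pathway, Wnt targets, YAP targets, mesenchymal transition genes, mitosis genes, DNA replication genes, p53 targets, interferon-stimulated genes, inflammatory and alarmin genes, ATF4 integrated stress response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, mitochondrially encoded genes, immediate early and heat shock genes, fibroblast, muscle, endothelial and leukocyte markers, columnar and secretory epithelium markers, replication-dependent histone genes and ribosomal protein genes.

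Whether libraries of the same replicate number belong together was checked by correlating them across genes after removal of group means. Of the compared groups only day 0 and KO day 4 passed a limit of 0.1 in each replicate (r = 0.31, 0.63 and 0.25, across genes, which are not independent replicates), so a replicate block was tried as an alternative. No paired analysis was possible for the PAS-seq and small RNA tables because they hold 1 distinct value per group. PAS-seq and small RNA calls are the authors', with no test run here. The relation of PAS-seq calls to mRNA change was tested with 1e+05 two-sided permutations over 4 relations with BH adjustment in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.

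The alternatives were pseudocounts of 0.1 and 2, a filter at 5 CPM and none, rescaling by the median of ratios, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, a fit of the compared groups alone, a replicate block and leaving out each library. A term for depth class (8 libraries above 30 M reads), the 10 shallow libraries alone, thinning to the shallowest library, log2 Alb as a covariate, leaving out libraries with Alb above 100 scaled CPM, leaving out genes that follow Alb (r of at least 0.8) and the replicate block in a fit of the compared groups alone were chosen after the data were seen. The tools were tested on simulated data, with reads drawn from the observed means and dispersions, KO day 4 set equal to day 0 and 200 of 12344 genes changed by known folds. limma recovered 62.7% of 1.5-fold, 83.6% of 2-fold and 90.9% of 4-fold changes, edgeR 61.2%, 85.1% and 92.4%, and DESeq2 68.7%, 85.1% and 92.4%. False calls were 17 of 175, 10 of 169 and 28 of 192.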

Results

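Cultured mouse esophageal basal cells carrying floxed alleles of Nudt21 and a tamoxifen-inducible Cre recombinase were profiled by mRNA sequencing, by poly(A) site sequencing (PAS-seq, which reads the 3' ends of transcripts) and by small RNA sequencing. Nudt21 encodes CFIm25, a subunit of cleavage factor Im, which takes part in the choice of poly(A) sites. The mRNA series held 18 libraries in 6 groups of 3. These were control cells given ethanol (day 0), cells given 4-hydroxytamoxifen for 2, 4 or 6 days (KO), and cells given 4-hydroxytamoxifen with doxycycline for 4 or 6 days, which the labels call hypomorph. PAS-seq covered 9 samples (control, KO day 4, hypomorph day 4) and small RNA sequencing 6 (control, KO day 4).

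Depth is given in M (mega) reads on listed genes. It came to 17.4, 19 and 16.3 M in the day 0 libraries, 65.5, 52.2 and 69.6 M at KO day 2, 50.9, 57.9 and 16.9 M at KO day 4 and 19.6, 16.3 and 53.3 M at KO day 6. The hypomorph libraries held 21.1, 54.4 and 21.3 M at day 4 and 19.6, 17.1 and 91.4 M at day 6. Transcripts of Alb, the liver serum protein albumin, ranged from 5.61 to 762 scaled CPM and differed within groups, with 517, 6.97 and 314 in the day 0 libraries and 36.9, 24.8 and 40.6 in the hypomorph day 6 libraries. Below, levels are scaled CPM given as mean ± SD (n = 3 libraries in every group), and log2 changes are limma estimates ± SE. A gene is said to have risen, fallen or differed where its limma adjusted p was under 0.05. List counts adjusted over the list alone are given where they differ from those adjusted over all genes. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

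**Figure D1:**
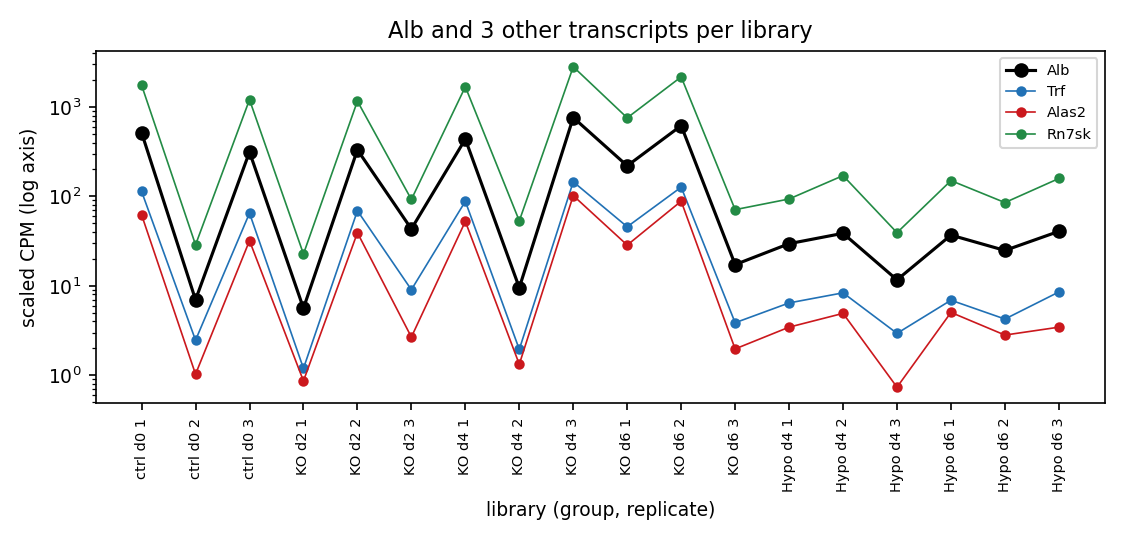
Level of Alb, Trf, Alas2 and Rn7sk in each of the 18 mRNA libraries (x axis, group and replicate; y axis, scaled CPM on a log axis); each point is a library and the lines only link the points of a transcript. Alb lay at 437, 9.53 and 762 scaled CPM in the KO day 4 libraries and at 29.6, 38.6 and 11.6 in the hypomorph day 4 libraries.

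Nudt21 mRNA (GRCm38 chromosome 8, 94019403 to 94037039, protein coding) lay at 12.9 ± 1.15 scaled CPM in control cells. It fell to 3.02 ± 0.228 at KO day 2, 3.03 ± 0.805 at KO day 4 and 1.71 ± 0.338 at KO day 6, which is 23.5%, 23.5% and 13.3% of the control mean. In hypomorph cells it fell to 5.01 ± 1.2 at day 4 (38.9%) and 2.77 ± 1.56 at day 6 (21.5%). The log2 changes against day 0 were -1.92, -1.94, -2.61 for KO days 2, 4 and 6 and -1.30 and -2.17 for hypomorph days 4 and 6 (SE 0.28 each), with limma adjusted p = 2.3e-05, 3.42e-06, 6.8e-09, 0.000949 and 1.96e-07. The authors' deposited table gave -2.09, -2.11, -2.90, -1.36 and -2.19. Counts are per gene, so they do not separate reads of the deleted exon from the rest of the transcript.

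Hypomorph and KO cells did not differ in Nudt21 past the threshold on either day. At day 4 the log2 difference was 0.64 ± 0.28 (limma adjusted p = 0.101), and a limma fit of the compared groups alone gave adjusted p = 0.0331, within a range of 0.0331 to 0.925 over all alternatives. At day 6 it was 0.43 ± 0.28 (limma adjusted p = 0.187). Hypomorph day 6 replicate 2 decided that value, with 0.999 scaled CPM from 16 reads, and without it the difference was 0.92 (limma adjusted p = 0.00121, the lowest of the alternatives run, which reached 0.696).

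**Figure D2:**
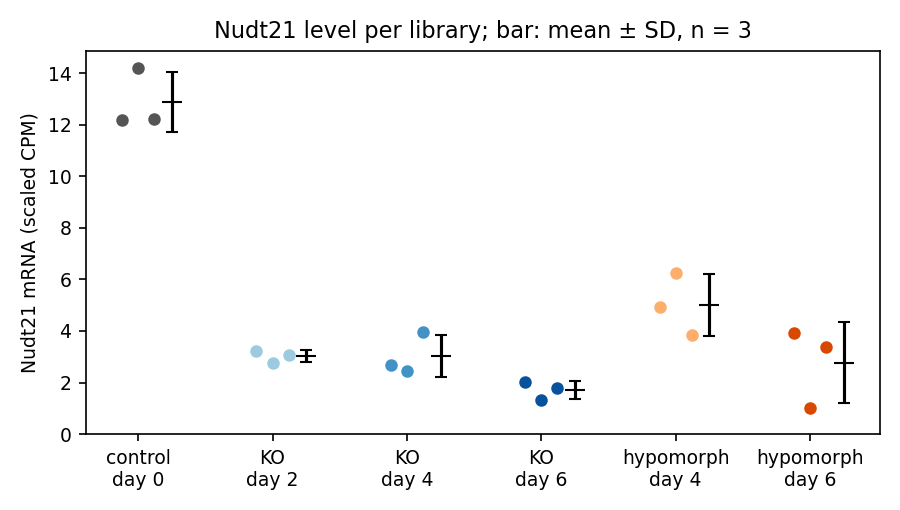
Nudt21 mRNA in each library by group (y axis, scaled CPM; x axis, group), with the mean and SD of 3 libraries beside the points. Control libraries averaged 12.9, and the KO and hypomorph groups averaged between 1.71 and 5.01.

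The first comparison, KO day 2 against day 0, asked what changed soon after Nudt21 loss. Tg, which encodes thyroglobulin, rose from 0.201 ± 0.348 to 6.5 ± 0.201 (log2 3.43 ± 0.23), and Ppbp, which encodes a platelet chemokine precursor, rose from 9.57 ± 1.32 to 44.7 ± 4.14 (log2 2.17 ± 0.10). Clec2f, a C-type lectin gene, rose from 62 ± 0.625 to 245 ± 6.2 (log2 1.97 ± 0.08), and Mss51 (log2 2.66 ± 0.19) and Lrrc69 (log2 2.07 ± 0.20) rose as well. Nudt21 and Cdhr1 (from 7.03 ± 4.02 to 1.6 ± 0.277, log2 -1.65 ± 0.40) were among the largest falls.

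Tgm3, which cross-links the cornified envelope, fell from 17.9 ± 27 to 0.464 ± 0.366, Gsdmc, a gasdermin gene, from 6.11 ± 7.34 to 0.381 ± 0.277 and Krtdap, a keratinocyte differentiation gene, from 10.5 ± 12.2 to 1.23 ± 0.557, with day 0 SDs that exceeded the means. Tgm3 lost its call in 8 alternatives (limma adjusted p = 0.0648 to 0.256), with a pseudocount of 2, the compared groups alone, a replicate block or depth class, and without day 0 replicate 1 or any KO day 2 library. Gsdmc lost it in 5 alternatives (limma adjusted p = 0.0536 to 0.156), with a pseudocount of 2 or depth class, and without day 0 replicate 1 or KO day 2 replicate 2 or 3. Krtdap lost it in 6 alternatives (limma adjusted p = 0.0516 to 0.277), with a pseudocount of 2, the compared groups alone or depth class, and without any KO day 2 library.

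Of 18 basal epithelial cell markers, 11 rose, 1 fell and 6 did not pass (median log2 0.28, limma camera adjusted p = 1.59e-05, adjusted p = 0.679 with an estimated correlation). Among those that rose were the laminin chain Lama3 (from 1226 ± 85 to 1823 ± 63.3, log2 0.57 ± 0.08) and the integrin Itga3 (log2 0.58 ± 0.08). Of 19 cleavage and polyadenylation factors, 6 rose, 1 fell and 12 did not pass (median log2 0.12, limma camera adjusted p = 0.0206, adjusted p = 0.877 with an estimated correlation, 8 and 2 adjusted over the list alone). The poly(A) polymerase gene Papolg (from 22.1 ± 2.86 to 39.8 ± 1.57, log2 0.84 ± 0.09), the CFIm subunit Cpsf6 (log2 0.38 ± 0.07) and the nuclear poly(A)-binding protein Pabpn1 (log2 0.41 ± 0.07) rose. Genes reported as CFIm25 3' UTR targets moved both ways, and of 12, 7 rose, 3 fell and 2 did not pass (median log2 0.23, mean -0.04, test downward, limma camera adjusted p = 0.923). The ATPase assembly gene Vma21 (from 56.9 ± 3.01 to 22.4 ± 0.928, log2 -1.32 ± 0.12) fell, and Wdr5 (log2 0.36 ± 0.07), a histone methyltransferase scaffold, rose.

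Of 19 ATF4 stress response genes, 0 rose, 5 fell and 14 did not pass (median log2 -0.14, limma camera adjusted p = 0.00142, adjusted p = 0.679 with an estimated correlation, 1 and 8 adjusted over the list alone). Aldh1l2 (from 34.6 ± 6.39 to 15.8 ± 0.623, log2 -1.09 ± 0.11), a mitochondrial folate enzyme, and Slc7a11 (log2 -0.42 ± 0.08), the cystine transporter, fell. Of 20 cholesterol synthesis genes, 9 rose, 2 fell and 9 did not pass (median log2 0.18, limma camera adjusted p = 0.0206, adjusted p = 0.877 with an estimated correlation, 10 and 2 adjusted over the list alone). The sterol carrier Stard4 (log2 -0.53 ± 0.08) fell. Of 14 hypoxia and glycolysis genes, 1 rose, 4 fell and 9 did not pass (median log2 -0.12, limma camera adjusted p = 0.0113, adjusted p = 0.679 with an estimated correlation, 1 and 6 adjusted over the list alone). The kinase Pdk1 (log2 -0.50 ± 0.08) fell. Inflammatory, squamous differentiation, p53, YAP, mitosis and miRNA biogenesis lists were not called at day 2, with limma camera adjusted p between 0.141 and 0.817.

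In all, 2342 of 12344 tested genes were called, 1442 up and 900 down, 192 of them by at least 2-fold. The authors' deposited table called 2400 genes, 1442 up and 958 down, and 2271 of them were called here. All 3 KO day 2 libraries held over 50 M reads and all day 0 libraries under 20 M. With a depth term 1074 genes were called (407 up), and 1071 (521 up) without the libraries with Alb above 100 scaled CPM, but 2168 (1345 up) in libraries thinned to the shallowest and 2348 with log2 Alb as a covariate. There were 1554 without day 0 replicate 1 and 1547 and 1382 without KO day 2 replicates 1 and 3. The share of called genes that rose was 61.6% and did not keep its side of 50% with edgeR, at 46.6%.

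At KO day 4, the day sampled for PAS-seq and small RNAs, changes against day 0 were larger. Tg rose from 0.201 ± 0.348 to 26.9 ± 0.875 (log2 5.39 ± 0.23) and so did Ppbp (log2 4.34 ± 0.10). Nek10 and Gp5, listed at 0 in all day 0 libraries, reached 11.5 ± 1.05 and 10 ± 0.829. The largest falls included the RNA-binding protein genes Hnrnpr (from 104 ± 4.99 to 15.6 ± 1.74, log2 -2.70 ± 0.10), Hnrnpll (log2 -2.33 ± 0.09) and Rbms3 (log2 -2.37 ± 0.21).

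Of 14 inflammatory and alarmin genes, 8 rose, 0 fell and 6 did not pass (median log2 0.70, limma camera adjusted p = 0.00551, adjusted p = 0.111 with an estimated correlation). The neutrophil chemokine gene Cxcl1 (from 10.2 ± 2.37 to 35.1 ± 2.88, log2 1.76 ± 0.15) and Nfkbia (log2 0.86 ± 0.08) were among them. Ccl20, a chemokine gene listed at 0 in all day 0 libraries, reached 2.08 ± 0.631. Of 12 interferon-stimulated genes, 7 rose, 0 fell and 5 did not pass (median log2 0.60, limma camera adjusted p = 0.0156, adjusted p = 0.536 with an estimated correlation, 8 and 0 adjusted over the list alone). Usp18 (from 0.126 ± 0.139 to 2.2 ± 0.224, log2 2.13 ± 0.31) and Parp14 (log2 1.31 ± 0.21) rose from low levels. Alb was above 100 scaled CPM in 2 of 3 KO day 4 and 2 of 3 day 0 libraries.

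Of 18 basal markers, 12 rose, 1 fell and 5 did not pass (median log2 0.24, limma camera adjusted p = 0.00551, adjusted p = 0.558 with an estimated correlation, 13 and 1 adjusted over the list alone). Pdpn (from 31.9 ± 5.8 to 116 ± 8.27, log2 1.86 ± 0.13), the membrane glycoprotein podoplanin, and Itga6 (log2 0.51 ± 0.07) rose. Of 24 squamous differentiation genes, 8 rose, 3 fell and 13 did not pass (median log2 0.23, limma camera adjusted p = 0.234, 8 and 4 adjusted over the list alone). Tgm1 (from 31.3 ± 9.47 to 64.8 ± 3.83, log2 1.08 ± 0.16), a cornified envelope transglutaminase, and the receptor Notch3 (log2 0.97 ± 0.11) rose. Among the 4 columnar and secretory epithelium markers, 3 rose, 0 fell and 1 did not pass (median log2 0.96, limma camera adjusted p = 0.00551, adjusted p = 0.111 with an estimated correlation). Epcam (from 42.5 ± 5.87 to 91.5 ± 4.26, log2 1.11 ± 0.10) and the keratins Krt18 (log2 1.16 ± 0.16) and Krt19 (log2 0.80 ± 0.10) rose. Of 3 leukocyte markers, 1 rose, 0 fell and 2 did not pass (median log2 0.47, limma camera adjusted p = 0.0367, adjusted p = 0.558 with an estimated correlation). The 1 that rose was Cd68 (log2 1.5 ± 0.08), a lysosomal membrane protein gene, whereas Ptprc lay at 8.52 ± 7.87 against 6.06 ± 5.33 and Laptm5 at 1.18 ± 0.937 against 1.49 ± 1.82, and both ran with Alb over the 18 libraries (r = 0.967 and 0.912).

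Among the CFIm25 targets, 2 rose, 4 fell and 6 did not pass (median log2 -0.01, limma camera adjusted p = 0.0639). Timp2 (from 75.8 ± 3.94 to 23.6 ± 1.91, log2 -1.66 ± 0.09), a metalloproteinase inhibitor, and Vma21 (from 56.9 ± 3.01 to 16 ± 0.914, log2 -1.80 ± 0.12) fell. Among cleavage and polyadenylation factors, 6 rose, 3 fell and 10 did not pass (median log2 0.06, limma camera adjusted p = 0.438). Papolg (log2 1.54 ± 0.09) and the termination factor Pcf11 (log2 0.67 ± 0.10) rose and Cstf2 (log2 -0.71 ± 0.08) fell. The miRNA-processing nuclease Drosha (log2 -0.51 ± 0.08) and Prkra (log2 -0.92 ± 0.13) fell. Of 20 cholesterol synthesis genes, 4 rose, 8 fell and 8 did not pass (median log2 -0.06, limma camera adjusted p = 0.0315, adjusted p = 0.811 with an estimated correlation). Nsdhl (from 168 ± 7.23 to 44.3 ± 4.6, log2 -1.91 ± 0.08) and Mvd (log2 -0.68 ± 0.07) fell. Among hypoxia and glycolysis genes, 1 rose, 7 fell and 6 did not pass (median log2 -0.34, limma camera adjusted p = 0.0241, adjusted p = 0.558 with an estimated correlation). Pdk1 (from 116 ± 8.06 to 49.8 ± 2.04, log2 -1.21 ± 0.08) and Bnip3 (log2 -0.92 ± 0.13) fell. Among ATF4 stress response genes, 3 rose, 11 fell and 5 did not pass (median log2 -0.29, limma camera adjusted p = 0.0668). Nupr1 (log2 1.80 ± 0.20) rose and Atf5 (log2 -0.72 ± 0.07) and Shmt2 (log2 -0.56 ± 0.07) fell.

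Cell cycle lists were not called at KO day 4. The ribonucleotide reductase gene Rrm2 (log2 1.01 ± 0.08) rose while the helicase genes Mcm2 (log2 -0.63 ± 0.08) and Mcm5 (log2 -0.65 ± 0.09) fell. In total 5675 of 12344 genes were called (2921 up, 2754 down, 918 by at least 2-fold). The authors' deposited table called 5588 genes, 2859 up and 2729 down, and 5526 of them were called here. edgeR (2813 up and 3039 down) and a depth term (2344 up and 2928 down) turned the side with more genes. With shallow libraries alone 3006 genes were called, and without the libraries with Alb above 100 scaled CPM 2803.

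KO cells at day 6 were then set against day 0. The interferon-induced GTPase gene Gbp2 (from 0.984 ± 0.302 to 36.7 ± 5.26, log2 4.66 ± 0.33) and the epidermal lipase gene Lipm (from 2.78 ± 2.34 to 70.4 ± 2.43, log2 4.65 ± 0.38) were among the largest rises, with Tg (from 0.201 ± 0.348 to 18.3 ± 2.93, log2 4.84 ± 0.23). Among the largest falls were Fst (from 85.7 ± 10.5 to 5.25 ± 2.22, log2 -3.99 ± 0.24), which encodes the activin inhibitor follistatin, and Hnrnpr (from 104 ± 4.99 to 8.12 ± 0.519, log2 -3.6 ± 0.10). Ereg, an EGF receptor ligand gene, fell from 31.6 ± 5.02 to 2.59 ± 0.237 (log2 -3.37 ± 0.12).

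Of 18 DNA replication genes, 0 rose, 17 fell and 1 did not pass (median log2 -1.79, limma camera adjusted p = 1.6e-18, adjusted p = 0.252 with an estimated correlation). The helicase subunit genes Mcm5 (from 261 ± 16 to 39.4 ± 4.38, log2 -2.71 ± 0.09) and Mcm7 (log2 -2.54 ± 0.08) were among them. Mitosis genes fell as well, and of 20, 1 rose, 18 fell and 1 did not pass (median log2 -1.26, limma camera adjusted p = 2.32e-12, adjusted p = 0.259 with an estimated correlation). Birc5 (log2 -2.26 ± 0.09) and the cyclin Ccna2 (log2 -2.07 ± 0.09) fell. Of 24 squamous differentiation genes, 20 rose, 1 fell and 3 did not pass (median log2 1.35, limma camera adjusted p = 0.0013, adjusted p = 0.464 with an estimated correlation). Their mean log2 level was 3.87, 5.08 and 3.57 in the day 0 libraries, where replicate 2 stood apart, and 5.55 to 5.98 at KO day 6. Sbsn (from 265 ± 17.6 to 536 ± 33.8, log2 1.01 ± 0.07) and Mal (log2 2.02 ± 0.18) rose, and the 1 that fell was Emp1 (log2 -1.23 ± 0.08). Among basal markers, 10 rose, 3 fell and 5 did not pass (median log2 0.26, limma camera adjusted p = 0.0525, 10 and 4 adjusted over the list alone). Col17a1 (log2 0.96 ± 0.08), the hemidesmosomal collagen, rose and Itga3 (log2 -0.96 ± 0.08) fell.

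The interferon-stimulated genes rose as a list, and of 12, 12 rose, 0 fell and 0 did not pass (median log2 2.08, limma camera adjusted p = 1.67e-05, adjusted p = 0.181 with an estimated correlation). They included Parp14 (from 1.82 ± 0.134 to 27.8 ± 3.66, log2 3.6 ± 0.21), Usp18 (log2 4.23 ± 0.31) and the RNA sensor gene Ddx58 (log2 1.37 ± 0.11). Of 14 inflammatory and alarmin genes, 10 rose, 2 fell and 2 did not pass (median log2 1.72, limma camera adjusted p = 0.0011, adjusted p = 0.181 with an estimated correlation, 11 and 2 adjusted over the list alone). Cxcl1 (from 10.2 ± 2.37 to 59 ± 1.1, log2 2.5 ± 0.15) and Nfkbia (log2 1.66 ± 0.08) rose. Ccl20 reached 6.11 ± 0.535 against 0 in every day 0 library. Among ATF4 stress response genes, 14 rose, 5 fell and 0 did not pass (median log2 0.72, limma camera adjusted p = 0.00156, adjusted p = 0.464 with an estimated correlation). Ddit3 (from 11.9 ± 0.773 to 71.1 ± 6.28, log2 2.53 ± 0.11), which encodes the stress factor CHOP, Nupr1 (log2 4.23 ± 0.20) and Chac1 (log2 2.20 ± 0.11) rose. Of 20 cholesterol synthesis genes, 1 rose, 17 fell and 2 did not pass (median log2 -0.78, limma camera adjusted p = 3.03e-13, adjusted p = 0.328 with an estimated correlation). Nsdhl (from 168 ± 7.23 to 22.6 ± 1.27, log2 -2.87 ± 0.08) and Mvd (log2 -2.26 ± 0.07) fell.

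Among the 12 CFIm25 targets, 2 rose, 9 fell and 1 did not pass (median log2 -0.64, limma camera adjusted p = 0.0142, adjusted p = 0.328 with an estimated correlation). Vma21 (from 56.9 ± 3.01 to 10.9 ± 0.79, log2 -2.33 ± 0.12) and Ccnd1 (from 432 ± 20.2 to 176 ± 25.1, log2 -1.30 ± 0.08), which encodes cyclin D1, fell. Cleavage and polyadenylation factors moved both ways, and 4 rose, 9 fell and 6 did not pass (median log2 -0.12, limma camera adjusted p = 0.579). Papolg (GRCm38 chromosome 11, 23860145 to 23895293) rose from 22.1 ± 2.86 to 139.7 ± 4.83 (log2 2.64 ± 0.09), and Cstf2 (log2 -1.79 ± 0.08) and Papola (log2 -0.87 ± 0.07) fell. Of 18 miRNA biogenesis and effector genes, 3 rose, 12 fell and 3 did not pass (median log2 -0.41, limma camera adjusted p = 0.279, 4 and 12 adjusted over the list alone). Drosha (from 90.4 ± 3.54 to 35.7 ± 1.86, log2 -1.33 ± 0.08) and Tarbp2 (log2 -1.04 ± 0.11) fell.

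Among 3 leukocyte markers, 1 rose, 0 fell and 2 did not pass (median log2 0.23, limma camera adjusted p = 0.0188, adjusted p = 0.464 with an estimated correlation). Cd68 rose from 71.6 ± 9.23 to 475 ± 27.8 (log2 2.73 ± 0.08). Across all 12344 genes, 4144 rose and 4632 fell (8776 called, 3270 by at least 2-fold). The side with more genes turned after rescaling by the median of ratios (4574 up and 4346 down) and with DESeq2 (4511 up and 4331 down). The authors' deposited table called 8644 genes, 4063 up and 4581 down, and 8626 of them were called here.

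Hypomorph cells at day 4 were set against day 0, which had no doxycycline. Tg rose from 0.201 ± 0.348 to 7.76 ± 0.86 (log2 3.66 ± 0.23), the uroplakin gene Upk1b (from 1.88 ± 0.548 to 18.7 ± 1.36, log2 3.03 ± 0.21) rose, and so did the serpin genes Serpinb9b (from 1.19 ± 0.291 to 12.8 ± 0.886, log2 2.99 ± 0.18) and Serpinb6c (log2 2.71 ± 0.24) and the neuropeptide gene Calcb (log2 2.75 ± 0.32). The axon guidance receptor gene Robo2 (from 16.8 ± 2.06 to 2.95 ± 0.642, log2 -2.34 ± 0.18), the galectin gene Lgals7 (from 71.1 ± 29.5 to 17.3 ± 1.26, log2 -1.93 ± 0.24) and the adhesion gene Flrt2 (from 246 ± 8.56 to 74.2 ± 1.56, log2 -1.72 ± 0.08) fell.

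Of 83 ribosomal protein genes, 44 rose, 0 fell and 39 did not pass (median log2 0.34, limma camera adjusted p = 7.09e-08, adjusted p = 0.569 with an estimated correlation, 54 and 0 adjusted over the list alone). Rpl17 (from 364 ± 9.3 to 491 ± 14.1, log2 0.43 ± 0.09) rose. Of 19 ATF4 stress response genes, 2 rose, 13 fell and 4 did not pass (median log2 -0.47, limma camera adjusted p = 7.68e-10, adjusted p = 0.37 with an estimated correlation, 2 and 14 adjusted over the list alone). Slc7a11 (from 119 ± 11.1 to 43.3 ± 1.04, log2 -1.44 ± 0.08), Aldh1l2 (log2 -1.12 ± 0.11) and the serine synthesis gene Psat1 (log2 -0.72 ± 0.08) fell. Among cholesterol synthesis genes, 1 rose, 10 fell and 9 did not pass (median log2 -0.16, limma camera adjusted p = 0.000182, adjusted p = 0.569 with an estimated correlation). Stard4 (from 333 ± 6.8 to 182 ± 2.78, log2 -0.87 ± 0.08) and Nsdhl (log2 -0.65 ± 0.08) fell. Among mitosis genes, 0 rose, 10 fell and 10 did not pass (median log2 -0.24, limma camera adjusted p = 0.000708, adjusted p = 0.569 with an estimated correlation, 0 and 11 adjusted over the list alone). Among DNA replication genes, 2 rose, 9 fell and 7 did not pass (median log2 -0.30, limma camera adjusted p = 0.0105, adjusted p = 0.569 with an estimated correlation, 2 and 10 adjusted over the list alone). Ccna2 (from 249.6 ± 7.63 to 166 ± 6.07, log2 -0.59 ± 0.09), Ccnb2 (log2 -0.40 ± 0.09) and Mcm5 (log2 -0.60 ± 0.09) fell. Among basal markers, 9 rose, 0 fell and 9 did not pass (median log2 0.21, limma camera adjusted p = 0.012, adjusted p = 0.569 with an estimated correlation). Col17a1 (from 2853 ± 208 to 3999 ± 270.4, log2 0.49 ± 0.08) and Itga3 (log2 0.42 ± 0.08) rose.

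Among interferon-stimulated genes, 4 rose, 0 fell and 8 did not pass (median log2 0.33, limma camera adjusted p = 0.137). Usp18 (from 0.126 ± 0.139 to 1.21 ± 0.424, log2 1.44 ± 0.31) rose from a low level. Among inflammatory and alarmin genes, 4 rose, 3 fell and 7 did not pass (median log2 0.33, mean -0.12, test upward, limma camera adjusted p = 0.727, 5 and 3 adjusted over the list alone). Cxcl1 (from 10.2 ± 2.37 to 18.3 ± 4.41, log2 0.81 ± 0.15) rose and S100a8 (from 2.15 ± 0.41 to 0.287 ± 0.15, log2 -1.76 ± 0.31), a calprotectin subunit gene, fell. Among CFIm25 targets, 2 rose, 2 fell and 8 did not pass (median log2 -0.02, limma camera adjusted p = 0.474). Vma21 (from 56.9 ± 3.01 to 26.3 ± 3.17, log2 -1.10 ± 0.12) fell and Pak1 (log2 0.64 ± 0.10) rose. Papolg rose from 22.1 ± 2.86 to 43.9 ± 2.43 (log2 0.98 ± 0.09).

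In this comparison 3908 of 12344 genes were called (2162 up, 1746 down, 434 by at least 2-fold). The authors' deposited table called 3859 genes, 2103 up and 1756 down, and 3777 of them were called here. edgeR (2073 up and 2183 down), DESeq2 (2188 up and 2292 down) and a depth term (1963 up and 1995 down) turned the side with more genes. In the hypomorph day 4 libraries Alb was lower than in 2 of the 3 day 0 libraries. With shallow libraries alone 2244 genes were called, and 2001 without the libraries with Alb above 100 scaled CPM.

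By day 6 hypomorph cells differed from day 0 at 8298 of 12344 genes, 4437 up and 3861 down (edgeR 4161 up and 4161 down), 2562 by at least 2-fold. Adm, which encodes the vasodilator peptide adrenomedullin (GRCm38 chromosome 7, 110627660 to 110629820), rose from 13.7 ± 1.86 to 385 ± 57.9 (log2 4.77 ± 0.12). The tight junction gene Cldn4 (from 5.46 ± 3.36 to 163 ± 15, log2 4.92 ± 0.28), the metalloproteinase inhibitor gene Timp3 (from 0.486 ± 0.436 to 28.3 ± 4.36, log2 4.98 ± 0.30) and the glycogen-binding gene Stbd1 (from 4.06 ± 1.1 to 129 ± 8.9, log2 4.85 ± 0.16) rose, and Car6, listed at 0 in all day 0 libraries, reached 13.1 ± 1.99. The histone chaperone gene Asf1b (from 66.9 ± 0.386 to 6.3 ± 2.51, log2 -3.37 ± 0.16), the exonuclease gene Exo1 (from 43 ± 1.34 to 4.42 ± 1.32, log2 -3.17 ± 0.13) and Ccne2 (log2 -3.15 ± 0.15), which encodes cyclin E2, fell. The authors' deposited table called 8212 genes, 4404 up and 3808 down, and 8133 of them were called here.

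Mitosis genes fell, and of 20, 0 rose, 20 fell and 0 did not pass (median log2 -1.80, limma camera adjusted p = 3.89e-31, adjusted p = 0.217 with an estimated correlation). Among them were Plk1 (from 147 ± 18.2 to 18.9 ± 2.4, log2 -2.92 ± 0.10) and Kif20a (log2 -2.28 ± 0.09). Among DNA replication genes, 0 rose, 16 fell and 2 did not pass (median log2 -1.97, limma camera adjusted p = 4.24e-24, adjusted p = 0.221 with an estimated correlation). Mcm5 (from 261 ± 16 to 38.3 ± 5.96, log2 -2.76 ± 0.09), Mcm7 (log2 -2.29 ± 0.08) and Rrm2 (log2 -1.93 ± 0.08) fell. Of 19 ATF4 stress response genes, 16 rose, 2 fell and 1 did not pass (median log2 1.60, limma camera adjusted p = 7.74e-15, adjusted p = 0.221 with an estimated correlation). Ddit3 (from 11.9 ± 0.773 to 138 ± 23.9, log2 3.47 ± 0.11), Aldh1l2 (log2 2.66 ± 0.11) and Chac1 (log2 2.58 ± 0.11) rose. Of 83 ribosomal protein genes, 80 rose, 1 fell and 2 did not pass (median log2 0.96, limma camera adjusted p = 5.84e-12, adjusted p = 0.622 with an estimated correlation). Rplp0 (from 1687 ± 83.6 to 3299 ± 419, log2 0.96 ± 0.08) rose. Of 21 p53 targets, 16 rose, 2 fell and 3 did not pass (median log2 0.74, limma camera adjusted p = 3.9e-05, adjusted p = 0.419 with an estimated correlation). The ubiquitin ligase gene Mdm2 (from 137 ± 4.45 to 422 ± 63.6, log2 1.61 ± 0.08), the BH3-only gene Pmaip1 (log2 2.35 ± 0.11) and the death receptor gene Fas (log2 2.36 ± 0.14) rose.

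Among cholesterol synthesis genes, 0 rose, 15 fell and 5 did not pass (median log2 -0.89, limma camera adjusted p = 5.84e-12, adjusted p = 0.411 with an estimated correlation, 0 and 16 adjusted over the list alone). Acat2 (from 269 ± 15 to 64.2 ± 5.48, log2 -2.06 ± 0.08) fell. Among hypoxia and glycolysis genes, 7 rose, 5 fell and 2 did not pass (median log2 0.22, limma camera adjusted p = 0.00273, adjusted p = 0.811 with an estimated correlation, 8 and 5 adjusted over the list alone). Ndrg1 (from 126 ± 12.3 to 759 ± 45.2, log2 2.59 ± 0.07) and the growth factor gene Vegfa (log2 1.21 ± 0.08) rose. Among squamous differentiation genes, 10 rose, 6 fell and 8 did not pass (median log2 0.50, limma camera adjusted p = 0.795). Sbsn (log2 1.04 ± 0.07) and Sprr1b (log2 1.80 ± 0.17) rose and Emp1 (log2 -2.03 ± 0.08) fell. Among interferon-stimulated genes, 4 rose, 1 fell and 7 did not pass (median log2 0.36, limma camera adjusted p = 0.75). Of inflammatory genes, Ptgs2 (from 148 ± 7.36 to 729 ± 78.6, log2 2.29 ± 0.08) rose and Cxcl5 (log2 -1.88 ± 0.29) fell.

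Among CFIm25 targets, 4 rose, 7 fell and 1 did not pass (median log2 -0.31, limma camera adjusted p = 0.252). Dicer1 (from 121 ± 2.41 to 59.4 ± 6.93, log2 -1.02 ± 0.08), the miRNA-processing nuclease, Vma21 (log2 -1.38 ± 0.12) and Ccnd1 (log2 -0.88 ± 0.08) fell. Among leukocyte markers, 1 rose, 0 fell and 2 did not pass (median log2 -0.46, mean 0.39, test upward, limma camera adjusted p = 0.0255, adjusted p = 0.811 with an estimated correlation). Cd68 rose from 71.6 ± 9.23 to 486 ± 21.5 (log2 2.76 ± 0.08).

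Hypomorph and KO cells were then compared with each other on the same day. At day 4 the matrix glycoprotein gene Tnc (108 ± 3.07 against 21 ± 3.77, log2 2.35 ± 0.22) and the type IV collagen genes Col4a2 (30.8 ± 1.86 against 5.85 ± 1.52, log2 2.33 ± 0.18) and Col4a1 (log2 1.96 ± 0.15) were higher in hypomorph cells. The aldehyde dehydrogenase gene Aldh3a1 (6.65 ± 0.384 against 79.8 ± 3.96, log2 -3.49 ± 0.17), Ppbp (log2 -2.25 ± 0.10) and the cytochrome P450 gene Cyp1b1 (log2 -2.26 ± 0.28) were lower. The CFIm25 target Timp2 (75.3 ± 5.16 against 23.6 ± 1.91, log2 1.65 ± 0.09) was higher, and of 12 such targets 4 were higher, 2 were lower and 6 did not pass (median log2 0.00, mean 0.22, test upward, limma camera adjusted p = 0.0331, adjusted p = 0.626 with an estimated correlation).

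Of 14 inflammatory and alarmin genes, 0 were higher, 8 were lower and 6 did not pass (median log2 -0.91, limma camera adjusted p = 9.55e-06, adjusted p = 0.0208 with an estimated correlation). No other list in the 7 comparisons was called with an estimated correlation. Nfkbia (72 ± 5.99 against 105 ± 8.74, log2 -0.54 ± 0.08) was lower, and Ccl20 lay at 0.208 ± 0.117 against 2.08 ± 0.631, a difference that did not pass with shallow libraries alone. Among interferon-stimulated genes, 0 were higher, 4 were lower and 8 did not pass (median log2 -0.38, limma camera adjusted p = 0.0297, adjusted p = 0.626 with an estimated correlation). Among mitosis genes, 0 were higher, 11 were lower and 9 did not pass (median log2 -0.27, limma camera adjusted p = 3.95e-05, adjusted p = 0.626 with an estimated correlation, 0 and 12 adjusted over the list alone). Cenpf (log2 -0.70 ± 0.10) was lower. Among p53 targets, 8 were higher, 2 were lower and 11 did not pass (median log2 0.15, limma camera adjusted p = 0.0297, adjusted p = 0.626 with an estimated correlation). Btg2 (171 ± 3.03 against 104 ± 6.68, log2 0.71 ± 0.08) and Ccng1 (log2 0.59 ± 0.08) were higher. Among ATF4 stress response genes, 2 were higher, 11 were lower and 6 did not pass (median log2 -0.28, limma camera adjusted p = 0.000373, adjusted p = 0.626 with an estimated correlation, 3 and 11 adjusted over the list alone). Slc7a11 (43.3 ± 1.04 against 99.3 ± 4.42, log2 -1.19 ± 0.08) and Trib3 (log2 -0.90 ± 0.16) were lower. Alb was below 40 scaled CPM in all hypomorph day 4 libraries and 9.53 to 762 in KO day 4.

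Among ribosomal protein genes, 8 were higher, 0 were lower and 75 did not pass (median log2 0.18, limma camera adjusted p = 0.0098, adjusted p = 0.71 with an estimated correlation, 1 and 0 adjusted over the list alone). The count was 3026 of 12344 genes (1711 higher in hypomorph, 1315 lower, 280 by at least 2-fold). Rescaling gave 1752 up and 1710 down, and DESeq2 turned the side with more genes (1865 up and 1979 down). The count was 622 with shallow libraries alone and 1118 without the libraries with Alb above 100 scaled CPM.

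At day 6 the hypomorph and the KO differed at 7988 of 12344 genes, 4651 higher and 3337 lower in hypomorph cells, 1977 by at least 2-fold. The excess of higher genes shrank after rescaling (4052 up and 4024 down) and turned with DESeq2 (4065 up and 4090 down). The urokinase receptor gene Plaur (46.5 ± 3.19 against 3.82 ± 0.914, log2 3.46 ± 0.14) and the ligand gene Wnt3 (14.3 ± 1.14 against 0.922 ± 0.0793, log2 3.38 ± 0.34) were higher. The cornified envelope gene Rptn (6.63 ± 1.29 against 102 ± 34.1, log2 -3.81 ± 0.52), Parp14 (1.86 ± 0.242 against 27.8 ± 3.66, log2 -3.58 ± 0.21) and the chemokine gene Cxcl3 (0.659 ± 0.375 against 11.4 ± 2.56, log2 -3.40 ± 0.24) were lower.

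Interferon-stimulated genes were lower in hypomorph cells, and of 12, 0 were higher, 12 were lower and 0 did not pass (median log2 -1.36, limma camera adjusted p = 1.23e-06, adjusted p = 0.117 with an estimated correlation). Ddx58 (16.3 ± 2.01 against 42 ± 1.44, log2 -1.35 ± 0.11) and Stat2 (log2 -1.37 ± 0.11) were examples. Of 14 inflammatory and alarmin genes, 1 was higher, 12 were lower and 1 did not pass (median log2 -1.66, limma camera adjusted p = 0.000132, adjusted p = 0.0726 with an estimated correlation). Cxcl1 (7.61 ± 0.691 against 59 ± 1.1, log2 -2.88 ± 0.15) and Nfkbia (log2 -1.47 ± 0.08) were lower, and the 1 that was higher was Ptgs2 (729 ± 78.6 against 227 ± 8.62, log2 1.68 ± 0.08). Of 24 squamous differentiation genes, 0 were higher, 19 were lower and 5 did not pass (median log2 -1.34, limma camera adjusted p = 9.76e-05, adjusted p = 0.469 with an estimated correlation). Tgm1 (16.8 ± 3.71 against 75.2 ± 8.96, log2 -2.15 ± 0.16) and Evpl (log2 -1.06 ± 0.12) were lower. Among mitosis genes, 0 were higher, 14 were lower and 6 did not pass (median log2 -0.52, limma camera adjusted p = 1.51e-05, adjusted p = 0.371 with an estimated correlation). Plk1 (18.9 ± 2.4 against 45.7 ± 5.88, log2 -1.25 ± 0.10) was lower.

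Of 21 p53 targets, 20 were higher, 0 were lower and 1 did not pass (median log2 0.81, limma camera adjusted p = 2.57e-06, adjusted p = 0.334 with an estimated correlation). Mdm2 (422 ± 63.6 against 172 ± 7.64, log2 1.29 ± 0.08) and the cell cycle inhibitor gene Cdkn1a (log2 1.07 ± 0.08) were higher. Of 19 ATF4 stress response genes, 17 were higher, 1 was lower and 1 did not pass (median log2 0.88, limma camera adjusted p = 2.57e-06, adjusted p = 0.334 with an estimated correlation). The serine synthesis gene Phgdh (508 ± 62 against 232 ± 2.29, log2 1.12 ± 0.07) and the amino acid transporter gene Slc7a5 (log2 1.00 ± 0.07) were higher. Of 83 ribosomal protein genes, 79 were higher, 0 were lower and 4 did not pass (median log2 0.74, limma camera adjusted p = 5.71e-08, adjusted p = 0.532 with an estimated correlation). Rps2 (2666 ± 341 against 1537 ± 67.9, log2 0.79 ± 0.08) and Rpl13a (log2 1.01 ± 0.09) were higher. Among hypoxia and glycolysis genes, 10 were higher, 1 was lower and 3 did not pass (median log2 0.73, limma camera adjusted p = 1.51e-05, adjusted p = 0.371 with an estimated correlation). Adm (385 ± 57.9 against 47.2 ± 2.88, log2 3.01 ± 0.12) and the glucose transporter gene Slc2a1 (log2 1.10 ± 0.07) were higher. Among YAP targets, 8 were higher, 2 were lower and 4 did not pass (median log2 0.46, limma camera adjusted p = 0.00463, adjusted p = 0.769 with an estimated correlation, 8 and 3 adjusted over the list alone). Cyr61 (99.9 ± 22.9 against 9.68 ± 1.03, log2 3.28 ± 0.14) and F3 (log2 2.53 ± 0.11) were higher. Rescaling the libraries by the median of ratios moved the median of all genes by 0.101 log2, the only comparison in which it moved by more than 0.1.

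Among CFIm25 targets, 8 were higher, 2 were lower and 2 did not pass (median log2 0.42, limma camera adjusted p = 0.144). Timp2 (116 ± 13.3 against 38.1 ± 2.48, log2 1.59 ± 0.09) and Pak2 (log2 0.76 ± 0.08) were higher and Tgfbr1 (log2 -0.81 ± 0.10) was lower. Papolg (58.3 ± 6.7 against 139.7 ± 4.83, log2 -1.26 ± 0.09) was lower and Cstf2 (log2 0.88 ± 0.08) was higher.

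**Figure D3:**
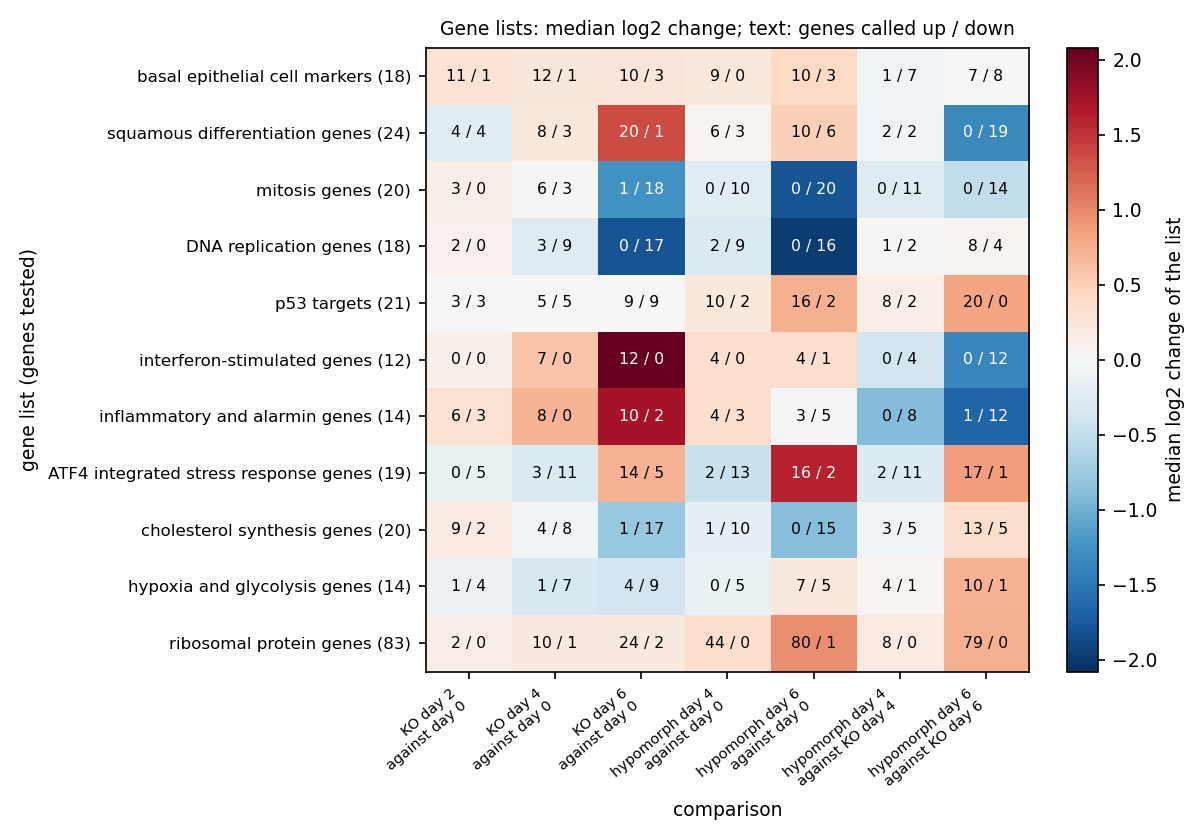
Median log2 change (colour) of 11 gene lists (y axis, genes tested in brackets) in 7 comparisons (x axis), with the number of members called up and down written in each cell. Interferon-stimulated genes ran from 2.08 at KO day 6 against day 0 to -1.36 in hypomorph against KO at day 6.

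Whether the step from day 4 to day 6 differed between hypomorph and KO was tested as an interaction in limma. ATF4 stress response genes moved further up in hypomorph cells, with 17 of 19 up and 0 down (median 1.03, limma camera adjusted p = 1.19e-13, adjusted p = 0.199 with an estimated correlation). Ribosomal protein genes gave 55 of 83 up and 0 down (median 0.56, limma camera adjusted p = 5.34e-06, adjusted p = 0.771 with an estimated correlation, 62 and 0 adjusted over the list alone). p53 targets gave 13 of 21 up and 1 down (median 0.51, limma camera adjusted p = 0.000127, adjusted p = 0.482 with an estimated correlation, 15 and 1 adjusted over the list alone). Hypoxia and glycolysis genes gave 9 of 14 up and 1 down (median 0.53, limma camera adjusted p = 0.000131, adjusted p = 0.495 with an estimated correlation). Interferon-stimulated genes gave 0 of 12 up and 8 down (median -1.09, limma camera adjusted p = 3.82e-05, adjusted p = 0.199 with an estimated correlation, 0 and 9 adjusted over the list alone). Against day 0 their median went from 0.60 to 2.08 in KO and from 0.33 to 0.36 in hypomorph cells. Squamous differentiation genes gave 0 of 24 up and 13 down (median -1.29, limma camera adjusted p = 0.000131, adjusted p = 0.495 with an estimated correlation, 0 and 17 adjusted over the list alone), with medians of 0.23 and 1.35 in KO and 0.06 and 0.50 in hypomorph cells. Mitosis genes gave 1 of 20 up and 6 down (median -0.23, limma camera adjusted p = 0.016, adjusted p = 0.771 with an estimated correlation, 1 and 5 adjusted over the list alone). YAP targets gave 7 of 14 up and 1 down (median 0.22, limma camera adjusted p = 0.0146, adjusted p = 0.947 with an estimated correlation). The test called 5636 of 12344 genes, 3385 up and 2251 down, an imbalance that shrank after rescaling (2960 up and 2827 down) and with DESeq2 (3034 up and 2817 down). The count was 2451 with shallow libraries alone and 3481 without the libraries with Alb above 100 scaled CPM.

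PAS-seq asked how poly(A) site choice in treated cells differed from control. In the authors' deposited table, 2135 of 4324 genes (49.4%) were called as shifted toward the proximal site in KO day 4 cells, 95 toward the distal site and 2094 not. Among genes called toward the proximal site, the authors' deposited table gave a median proximal share of 13.4% in control and 77.7% in KO. For genes called toward the distal site the same table of the authors gave 83% and 29%, and for genes not called 22.9% and 33.3%. The share was higher in KO for 3611 of 4322 genes (83.5%). In hypomorph cells the authors' deposited table called 942 genes toward the proximal site, 38 toward the distal site and 3344 not.

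The largest proximal shifts in the authors' deposited table were in the lipid flippase gene Atp8a1, Rmnd5a, Vcpip1 and Yeats4, each from 0% to 100%, and in the kinase gene Mapk8, from 0% to 97.3%. Among the largest distal shifts in the authors' deposited table were those in the synaptic scaffold gene Homer1, from 100% to 5.88%, the splicing regulator gene Qk, from 100% to 11.4%, Calu, from 95% to 7.5%, and Itsn2, from 91.6% to 4.62%. Of the reported CFIm25 targets, 10 were listed, and 6 were called toward the proximal site in KO, for example from 17.7% to 93.8% for Vma21, 38.9% to 94.4% for Wdr5, 13.1% to 67.4% for Ccnd1, 50% to 95.9% for Igf1r and 32% to 68% for Pak2. Dicer1, Pak1 and Psmb2 were not called. Yeats4, Homer1, Igf1r and Pak2 were not called in hypomorph cells.

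Of the genes called toward the proximal site, 931 were called in both KO and hypomorph. Both were set against the same controls, and 836 of the hypomorph calls fall on genes listed with equal KO and hypomorph ratios, so the overlap is not read as agreement. A further 1191 were called toward the proximal site in KO and neither way in hypomorph, and 20 genes were called in opposite directions, differences the table does not test. The table holds a single pooled value per gene and group without replicates or read depth, so no error or interval is given. The KO and hypomorph columns held the same ratio (within 1e-06, relative) in 3397 genes (78.6%), every gene named here included, so hypomorph levels are not used and the KO shares of those genes may belong to either group.

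**Figure D4:**
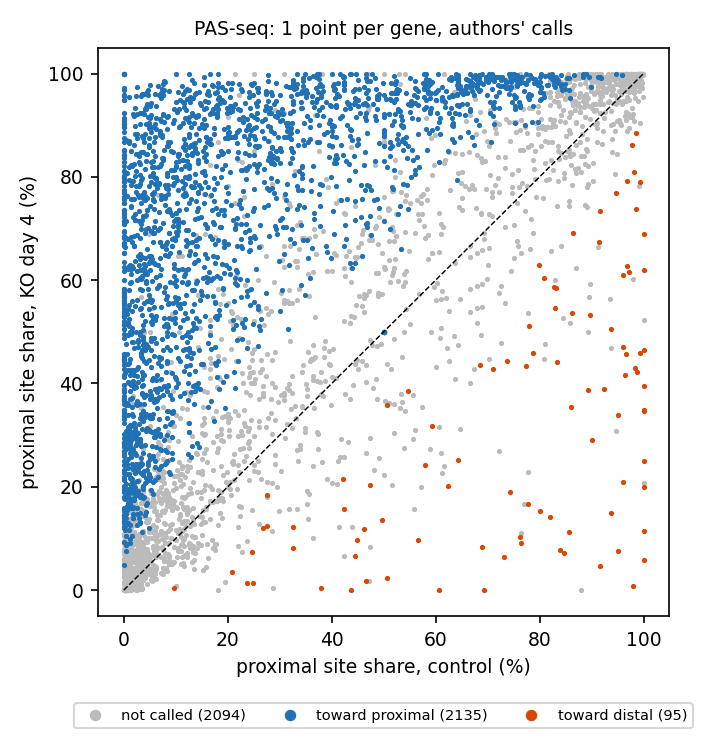
Proximal site share of each gene in control (x axis, %) and KO day 4 (y axis, %), 1 point per gene, coloured by the authors' call. Of 2135 genes called toward the proximal site, 2132 had a higher share in KO and lie above the dashed line of equal shares, and the 95 called toward the distal site lie below it.

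Site choice was then set beside mRNA level at day 4. Genes called toward the proximal site in KO had a median log2 mRNA change of -0.08, against 0.02 for genes not called, a difference of -0.09 (two-sided permutation p = 1e-05, the smallest possible, BH adjusted p = 2e-05). Of them 754 of 2135 fell, against 468 of 2094 genes not called, and 476 rose. For the distal group the difference was -0.11 (permutation p = 0.00656, BH adjusted p = 0.00875), with 33 of 95 down. In hypomorph cells the difference was -0.07 for the proximal group (permutation p = 1e-05), with 301 of 942 down. Of the 942, 931 were also KO calls, so it is no independent test. The distal group gave -0.10 (permutation and BH adjusted p = 0.0551). These 4 relations run across genes, which are not independent replicates.

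Small RNA sequencing asked which miRNAs changed in KO day 4 cells. The authors' deposited table called 18 of 682 miRNAs up and 28 down. The largest rises in the authors' deposited table, in scaled CPM, included the epidermal differentiation miRNA miR-203-3p from 3626 to 15329 (log2 change 2.08, FDR 7.92e-36), and its neighbour miR-203b-5p from 395 to 1426 (log2 change 1.85, FDR 1.21e-21). The authors' deposited table also had miR-7a-5p from 6289 to 15132 (log2 change 1.27, FDR 4.16e-15), miR-7b-5p from 36.7 to 102 (log2 change 1.48, FDR 3.19e-07), miR-129-5p from 134 to 321 (log2 change 1.26, FDR 6.48e-08) and miR-7649-5p from 20.5 to 93.5 (log2 change 2.19, FDR 3.56e-13) up. Falls in the authors' deposited table included miR-365-2-5p from 82.3 to 17.7 (log2 change -2.22, FDR 1.29e-12), miR-205-3p from 699 to 174 (log2 change -2.0, FDR 5.31e-22), miR-6539 from 673 to 171 (log2 change -1.98, FDR 1.02e-20), miR-504-5p from 84.1 to 30.4 (log2 change -1.47, FDR 2.18e-06), miR-125b-1-3p from 506 to 226 (log2 change -1.16, FDR 1.32e-07) and let-7a-1-3p from 369 to 177 (log2 change -1.06, FDR 4.4e-06). At a mean of at least 50 scaled CPM, 31 of 175 miRNAs were called, 14 up and 17 down.

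By family, the calls in the authors' deposited table were 0 up and 4 down of 20 members of the let-7 family (of the 4, let-7a-1-3p and let-7c-2-3p hold the same values and are a single measurement), 0 up and 2 down of 18 of the miR-17-92 cluster and its paralogs, 0 up and 2 down of 9 of the miR-200 family and 1 up and 3 down of 16 epithelial and squamous miRNAs. The miR-99 and miR-125 clusters gave 0 up and 1 down of 9, and the miR-29 and miR-30 families 0 up and 1 down of 16. In the authors' deposited table no member was called among 7 of the miR-34 and miR-449 family, 13 of the miR-15 and miR-16 family and 10 of the miR-181 and miR-221 families. Summed let-7 levels in the authors' deposited table were 378235 scaled CPM in control and 401581 in KO. The 3 columns of a group held the same value for every miRNA, so no spread between libraries could be taken from the table.

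**Figure D5:**
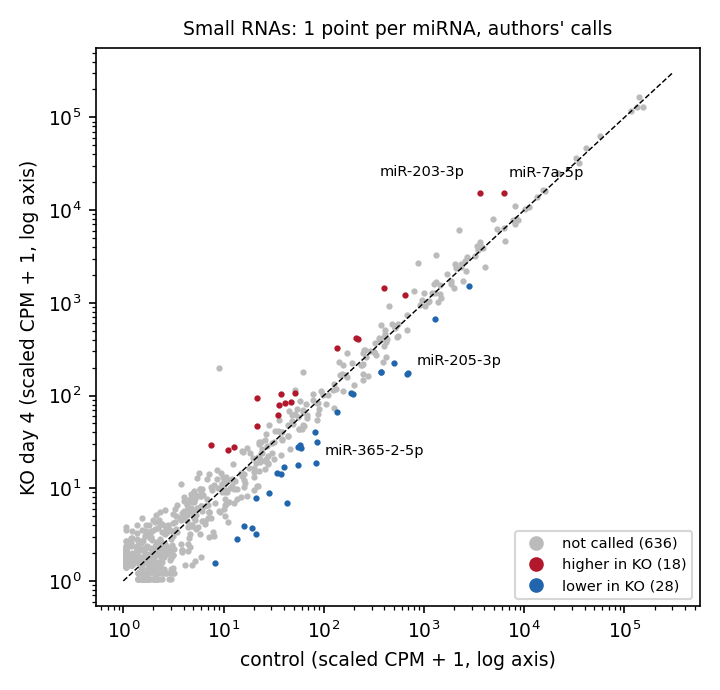
Level of each miRNA in control (x axis) and KO day 4 (y axis), both as scaled CPM plus 1 on log axes, 1 point per miRNA, coloured by the authors' call. The 18 called up lie above the dashed line of equal levels and the 28 called down below it, with miR-203-3p at 3626 and 15329.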

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

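The Alb covariate and the thinned libraries were chosen after the data were seen, and the other tests given here were set before their results were seen. At day 4, 3026 genes differed between hypomorph and KO, with Tnc and Col4a2 higher and Aldh3a1 and Ppbp lower in hypomorph cells, and at day 6 7988 genes did, with Parp14 and Rptn lower. Both are of interest because Nudt21 fell in both groups and limma tested the difference. Equal loss was not shown (hypomorph 38.9% and 21.5% of day 0, KO 23.5% and 13.3%). Only the real split of the 6 libraries, 1 of 10, gave as many genes each day, and 10 are too few for a share under 0.05. The highest other split called 0 genes in limma at day 4 (805 at an unadjusted p under 0.05, against 4475 in the real split) and 0 at day 6 (1258 against 8321).

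The interaction test called 5636 genes whose change from day 4 to day 6 differed between hypomorph and KO, with 17 of 19 ATF4 stress response and 55 of 83 ribosomal protein genes up and 8 of 12 interferon-stimulated genes down in hypomorph cells relative to KO. None of the 3 lists passed with an estimated correlation (adjusted p = 0.199, 0.771 and 0.199). Of 100 within-day splits drawn, 4 gave as many genes, the real one included. The highest other split gave 6265, and the next gave 6185 and 5867. Those 3 left the day 6 libraries as labelled, or exchanged the groups whole, and moved 1 or 2 day 4 libraries, so the count follows a structure of the samples, the difference at day 6. The splits therefore leave open whether chance gave the difference between the steps.

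In each comparison with day 0 the real split was again the only 1 of 10 with as many genes, with the same limit. The real splits called 2342, 5675, 8776, 3908 and 8298 genes for KO days 2, 4 and 6 and hypomorph days 4 and 6. The highest other splits called 0 genes in limma each, with 937, 1076, 1133, 1059 and 1252 genes at an unadjusted p under 0.05 against 3883, 6469, 9000, 5135 and 8587 in the real splits. edgeR and DESeq2 were not run on the splits.

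Interferon-stimulated and inflammatory genes, such as Parp14, Ddx58 and Cxcl1, were lower in hypomorph than in KO cells at day 6, though neither list passed with an estimated correlation (adjusted p = 0.117 and 0.0726). RNA from an outside mixture is argued against. The KO library with least Alb lay 1.51 log2 above the highest hypomorph library over both lists. With log2 Alb as a covariate 24 of 26 members passed. Depth is argued against too, as 24 of 26 passed in thinned libraries. More differentiated KO cells may contribute. Correlation of these genes with squamous genes over 12 libraries after removal of group means left this open (r = 0.29, rho = 0.22, permutation p = 0.201, r = 0.35 without the 2 farthest libraries). At day 4 squamous means were close (log2 4.25 to 4.39 in KO, 4.23 to 4.27 in hypomorph). Those of these genes were not (2.44 to 2.59, 1.70 to 1.90), which argues against differentiation as the whole cause that day. The hypomorph state and doxycycline stay open, untested.

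Ribosomal protein genes, such as Rps2 and Rpl13a, were higher in hypomorph than in KO cells at day 6, by a median of 0.74 log2, though the list did not pass with an estimated correlation (adjusted p = 0.532). Gene length and level are argued against as the whole cause, since 1000 sets of genes matched to them gave medians of 0.21 to 0.45 (95%), the highest 0.53. Scaling is argued against too, since the median was 0.64 after rescaling by the median of ratios. The hypomorph state itself or doxycycline stays open, untested.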

How the results depend on the processing

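Depth class as a covariate, shallow libraries alone, thinning, the log2 Alb covariate, leaving out the libraries with Alb above 100 scaled CPM or the genes that follow Alb, and the replicate block in a fit of the compared groups alone were chosen after the data were seen. Nudt21 fell against day 0 under every alternative run, with its KO and hypomorph levels between 12.1% and 43.4% of day 0 when single libraries were left out. Of 473 results for named genes, 464 were called, and 377 of those kept their call in all alternatives run. In all, 9644 of 9908 alternatives for named genes kept direction and side of the threshold. Squamous genes at KO day 2 (Tgm3, Gsdmc, Krtdap) and many genes that differed between hypomorph and KO at day 4 (Crim1 and Xpo5 with shallow libraries alone) were among those that did not.

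The number of genes called in the 7 comparisons (KO days 2, 4 and 6 and hypomorph days 4 and 6 against day 0, hypomorph against KO at days 4 and 6) was 2458, 5852, 8767, 4256, 8322, 3429 and 8011 with edgeR and 2845, 6006, 8842, 4480, 8447, 3844 and 8155 with DESeq2, within 1.5 times those of limma. Leaving out 1 library gave 1382 to 2353 at KO day 2, 5024 to 5265 at KO day 4, 8330 to 8558 at KO day 6, 2890 to 3599 and 7839 to 8089 at hypomorph days 4 and 6, 2117 to 2659 and 7427 to 7718 in hypomorph against KO and 5105 to 5638 in the interaction. The KO day 2 count moved by more than 1.5 times without day 0 replicate 1 (1554), KO day 2 replicate 1 (1547) and KO day 2 replicate 3 (1382). With a replicate block the counts were 2466, 5770, 8814, 3995, 8325, 3131 and 8041, and 5657 for KO day 4 with the compared groups alone.

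Leaving libraries out by depth or Alb lowered several counts, and these fits also hold fewer libraries. No KO day 2 library was shallow, so that fit was not possible there. Shallow libraries alone gave 3006 at KO day 4, 2244 at hypomorph day 4, 622 in hypomorph against KO at day 4 and 2451 in the interaction. Without the libraries with Alb above 100 scaled CPM the counts were 1071 at KO day 2, 2803 at KO day 4, 2001 at hypomorph day 4, 1118 in hypomorph against KO at day 4 and 3481 in the interaction. With log2 Alb as a covariate the counts of the 7 comparisons were 2348, 5907, 8899, 3792, 8330, 2825 and 7947, and without the genes that follow Alb 2431, 5759, 8801, 4009, 8347, 3106 and 8015. The groups left with 1 library in the fits on fewer libraries are assumed to vary like the others. With depth class as a covariate KO day 2 gave 1074 genes (407 up, 667 down), where depth class and group coincide. Thinned to the shallowest library, the 7 comparisons gave 2168, 5485, 8635, 3672, 8154, 2832 and 7796 genes, and 2056 of 2342 calls at KO day 2 were shared. The share of called genes that rose at KO day 2 was 61.6% in limma, 54.8% after rescaling, 46.6% with edgeR and 53.8% with DESeq2. With edgeR, DESeq2 or rescaling the side with more called genes turned in 6 of the 7 comparisons and was even at hypomorph day 6 with edgeR. It also turned with depth class at KO days 2 and 4 and hypomorph day 4, with shallow libraries alone at KO day 4 and hypomorph day 6, and without the libraries with Alb above 100 scaled CPM at KO day 2. At KO day 4 the compared groups alone and leaving out KO day 4 replicate 2 turned it. It did not turn in the interaction.

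Of 54 calls of gene lists by limma camera, 1 was called with an estimated correlation (inflammatory and alarmin genes, lower in hypomorph than in KO at day 4), and 93 lists were called by fry, which tests a list on its own. Under fry the ribosomal protein genes no longer passed in hypomorph against KO at day 4. The leukocyte markers Ptprc and Laptm5, which were not called and ran with Alb, changed direction. Leaving out 1 library gave log2 changes of -0.95 to 1.84 for Ptprc and -0.75 to 0.75 for Laptm5 at KO day 4, -1.19 to 1.2 and -0.86 to 0.65 at KO day 6 and -1.21 to 0.29 for Laptm5 at hypomorph day 6. Ptprc at KO day 4 turned without day 0 replicate 2 and without KO day 4 replicate 1 or 3, and at KO day 6 without day 0 replicate 2 or KO day 6 replicate 2. Laptm5 at KO day 4 was -0.0545 with a pseudocount of 2, -0.38 with edgeR, -0.34 with DESeq2, -0.0453 thinned and -0.17 with the Alb covariate. At KO day 6 it was 0.15 with depth class and 0.56 with shallow libraries alone, and at hypomorph day 6 0.14 with the Alb covariate.

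For PAS-seq and small RNA the tables hold 1 distinct value per group, so a stricter threshold, a coverage minimum, a pseudocount, low-count filters, rescaling, edgeR, DESeq2, a replicate block, the compared groups alone and leaving out replicates were not run, and a direct PAS-seq comparison of hypomorph with KO was not possible. Of the PAS-seq genes called in KO, 2205 of 2230 shifted by at least 10 points, and 31 miRNA calls had a mean of at least 50 scaled CPM. The depth of both tables is unknown. In the mRNA libraries a gene at 1 scaled CPM holds few reads in the shallow libraries, which limits genes such as Usp18 and Tgm3.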

Other observations

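The tests of an outside mixture and of depth for the liver and blood transcripts and the level-matched test of miRNA arms were chosen only after the result was seen, as were the PAS-seq list tests. Of 4 columnar and secretory epithelium markers at KO day 2, 3 rose, 0 fell and 1 did not pass (median log2 0.78, limma camera adjusted p = 0.000616, adjusted p = 0.18 with an estimated correlation). At hypomorph day 4, 2 rose, 0 fell and 2 did not pass (median log2 0.32, limma camera adjusted p = 0.00147, adjusted p = 0.37 with an estimated correlation). Of 10 immediate early and heat shock genes at hypomorph day 4, 5 rose, 0 fell and 5 did not pass (median log2 0.43, limma camera adjusted p = 0.0302, adjusted p = 0.482 with an estimated correlation, 6 and 0 adjusted over the list alone).

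Marker lists of other cell types had few tested members. The smooth muscle actin gene Acta2 changed by -0.60 log2 at KO day 2 and -0.86 at hypomorph day 4, rose by 2.87 at KO day 6 and 3.05 at hypomorph day 6, and differed by -1.17 in hypomorph against KO at day 4. Acta1 was not called in limma. The endothelial receptor gene Tek rose by 1.09 at KO day 4 and 1.15 at KO day 6, and differed by -1.66 in hypomorph against KO at day 6. Egfl7 changed by -1.30 at KO day 6 and differed by 0.71 and 1.53 in hypomorph against KO at days 4 and 6. The fibroblast gene Fbln1 changed by -0.43 at hypomorph day 6 and differed by -0.31 from KO that day, and Col3a1 was not called in limma.

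Of 15 gene lists tested against the other genes of the PAS-seq table with Fisher's exact test (two-sided), ribosomal protein genes were called toward the proximal site less often, in 5 of 46 (odds ratio 0.123, BH adjusted p = 6.28e-07). All 5 listed Notch pathway genes were called toward the proximal site (BH adjusted p = 0.22), as were 6 of 7 YAP targets (BH adjusted p = 0.263), and neither passed.

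KO and hypomorph changes against day 0, which share the same 3 control libraries, had a correlation across genes of 0.64 at day 4 and 0.66 at day 6, against 0.49 and 0.51 in simulations of shared controls alone (covariances 0.172 and 0.586, against 0.0252 and 0.0264). At day 4, 1575 genes such as Tg rose in both and 1324 such as Vma21 fell in both, where independent calls would give 512 and 389.5, and 40 moved apart. At day 6 the counts were 2786 and 2815, against 1489.5 and 1449, with 826 apart. Simulations of shared controls alone called 0 genes in both at either day. That value leaves out the effects, and 3 controls are too few to split, so a part of the excess over independent calls that comes with the shared controls stays open.

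Transcripts of liver and blood cells, such as Alb, Trf and Alas2, varied together between libraries of the same group. Depth is argued against, since Alb differed 74.1-fold among the 3 day 0 libraries of like depth. RNA of an outside mixture is a candidate source. Over 60 markers the median slope of log2 level on log2 Alb was 0.69 (95% interval 0.58 to 0.73, classes 0.53 to 0.86), between the bounds for and against it. Low Apoa1 gave 0.36 and abundant Rn7sk 0.98, so slopes partly follow level and do not decide. Ass1 (-0.01) lay at 153 to 262 scaled CPM at low and high Alb alike, so it does not bear on a mixture. Differentiation state was not decided, since squamous genes ran against Alb in 3 of 4 groups of only 3 libraries, and their means were 4.39 and 4.36 in the KO day 4 libraries with Alb at 9.53 and 762. Of 318 genes that follow Alb, 4 to 37 were among the genes called in a comparison.

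Genes called toward the proximal site, such as Vma21 and Ccnd1, had lower mRNA changes than genes not called and were longer (median 4664 against 2962 bases). Length is argued against as the whole cause (-0.0835 log2 against length-matched genes, 95% interval -0.12 to -0.06, and -0.09 unmatched). Genes called toward the distal site were lower too (by -0.11), so the difference was not specific to a direction. Counts are per gene, so lost 3' sequence is not told from lost mRNA. A direct effect of site choice stays open, untested.

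In the authors' deposited table, the less abundant arm of a miRNA hairpin, such as miR-205-3p and let-7a-1-3p (equal to let-7c-2-3p, also counted), had the lower change in 57 of 75 hairpins. The median difference was -0.48 log2 (95% interval -0.85 to -0.27, sign-flip permutation p = 1e-05, the smallest possible). Hairpins, some sharing an arm, are not independent replicates. The authors called 16 less abundant arms down and, of the abundant arms, 4 up and none down. Noise of low levels may contribute and stays open, since 44 less abundant arms differed from abundant arms of like level by -0.28 (95% interval -0.62 to -0.09).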
